A study of Mus musculus with 31 samples.

How the data were processed

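Expression was measured by RNA sequencing in 21 libraries. Of these, 15 came from the dentate gyrus of Nestin-EGFP mice, in which an enhanced green fluorescent protein (EGFP) marks neural stem cells and their offspring. The mice received midazolam (MDZ, a benzodiazepine sedative that strengthens signalling through GABA-A receptors) at 10 mg/kg, or water, on postnatal days 7, 8 and 9. EGFP-positive cells were sorted by flow cytometry at postnatal day 10 (P10; Control P10 and MDZ P10) or at 8 weeks (Control 8w, MDZ 8w and RUN MDZ 8w, the last from exposed mice kept with a running wheel). The other 6 libraries came from long-term cultures of mouse neural stem cells, started from embryonic day 11 cortex and passaged more than 20 times. They carried a lentivirus for the M2rtTA transactivator alone (Control culture) or with a second lentivirus for Flag-tagged Egr1 (Egr1 culture). Every group had 3 libraries. Of the 31 samples listed, the 10 ATAC and chromatin immunoprecipitation samples were not analysed here. No group of unexposed running mice was listed.

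Per the labels' protocols, a P10 library was made from 50000 cells of 1 mouse and an 8-week library from about 30000 cells pooled from 3 to 5 mice, with a direct mRNA isolation kit and a directional library kit. Nothing in the labels says that the cultured samples were separate cultures. All p-values measure the spread between these samples, which may be technical in culture. The deposited P10 files hold FPKM values and the deposited 8-week and culture files hold TPM values. No label states these units. They were read from the values: the 8-week and culture libraries each summed to 1000000, and the P10 libraries summed to different totals over the same 24062 gene names. The authors aligned reads to mm10 per the submitters' processing notes, which also name TopHat, Bowtie2 and DESeq2 without role or version. The program that made the values, its annotation, its strand setting and any filter are not given in the sources used here. Genes that overlap or have near-identical copies are therefore uncertain. The culture files hold 24322 gene names, so they came from another annotation.

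No read counts were used here, so sequencing depth is known only in part. P10 totals ran from about 241500 to 252300 FPKM. Low P10 and culture values fall in steps of whole fragments, and the most frequent ratio of values between 0.005 and 0.1 gave the relative depth of a library. Against the deepest P10 library (MDZ P10 replicate 3), relative depth was 0.712, 0.57 and 0.807 in Control P10 replicates 1 to 3, and 0.722 and 0.796 in MDZ P10 replicates 1 and 2. The culture libraries lay between 0.901 and 0.966 of the deepest one. The depth of the 8-week libraries is unknown.

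Control 8w replicates 2 and 3 shared 99.12% of their detected genes, and 8 genes above 5 TPM in one were listed at 0 in the other. Their Spearman correlation was 0.9919, and the robust SD of their log2 ratio at 20 to 50 TPM was 0.263. Against replicate 1 the corresponding values were 75.48% and 75.38% of genes shared, 2141 and 2261 genes at 0 on one side, and robust SDs of 1.39 and 1.33. The other 8-week pairs within a group shared 81.5% to 92.3% of genes. Without counts, sampling noise cannot be computed for these files. Replicates 2 and 3 differed by less than any other 8-week pair and may be repeat deposits of one library, so their mean was used as 1 sample and Control 8w had n = 2. This choice was made after the files were seen, and the counts with both kept apart are given with the alternatives.

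Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. That plan assumed read counts and a count-based test. For normalized values it named limma-trend on log2(value + 1), which was used throughout (limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package). A fold change on this scale understates the change of low genes. Genes with a mean of at least 1 in the fit were tested, a filter set after the files were seen, and some fits under these settings had been looked at before the added alternatives were listed. P-values were adjusted by Benjamini-Hochberg, and a gene passed at an adjusted p below 0.05. The P10 comparison used the 6 P10 libraries, the culture comparison the 6 culture libraries, and the 8-week comparisons all 8-week samples with one estimate of the spread. The 8-week groups did not vary alike. At 20 to 50 TPM the robust SD of the log2 ratio within MDZ 8w was 0.339 to 0.368. It was 0.577 to 0.668 within RUN MDZ 8w, and 1.39 and 1.33 for Control 8w replicate 1 against replicates 2 and 3. One spread may therefore give p-values that are too small against Control 8w and too large for RUN MDZ 8w against MDZ 8w. The planned test of whether the midazolam effect differed between ages used one spread for both ages. On simulated data with 200 changed genes it recovered 83 and made 59 false calls among 14301 genes, while a version with a separate spread per age recovered 62 with 5 false calls among 14145 genes. These data were drawn with a separate spread for each age, as the second version assumes, so the planned test was at a disadvantage. The separate-spread version was put first, after seeing the data. Ages were compared only through changes within each age, since the FPKM and TPM tables were normalized separately. For that test each P10 library was rescaled to a sum of 1000000. Control 8w against Control P10, although planned, was not run for that reason.

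The limma step was tested on simulated libraries with 50 genes changed at each of 4 sizes. Genes were drawn independently of each other, with the spread estimated by the fit. At log2 changes of 0.5, 1, 2 and 4 it recovered 96%, 100%, 100% and 100% in the P10 simulation (12845 genes) and 66%, 96%, 98% and 100% in the culture simulation (12311 genes). It recovered 0%, 0%, 38% and 82% for MDZ 8w against Control 8w (14759 genes), 0%, 4%, 26% and 80% for RUN MDZ 8w against MDZ 8w (14738 genes), and 0%, 4%, 28% and 72% for RUN MDZ 8w against Control 8w (14741 genes). False calls numbered 16, 4, 6, 3 and 2 in the same order. In these simulations changes of 2 or less on the log2 scale were thus mostly missed at 8 weeks. The rates hold for 200 changed genes, which eases the adjusted threshold, and need not hold for the real data. Egr1 at P10 did not pass at log2 0.62 ± 0.11, while Prox1 passed at -0.90 in MDZ 8w against Control 8w.

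The 27 gene lists (570 genes) covered S phase, G2/M and mitosis, CDK inhibitors, Notch, BMP and Id signalling, radial glia-like stem cell markers, mature astrocyte markers, intermediate progenitor and neuroblast markers, mature neuron markers, GABA receptors and handling, immediate early genes, Egr1 targets known from other systems, EGF, FGF and MAP kinase feedback, ligands and receptors linked to running, fatty acid oxidation, glycolysis, cholesterol synthesis, p53 targets, interferon response, chromatin regulators, and sex-linked genes. Lists for other cells the sort could hold were oligodendrocyte precursors, mature oligodendrocytes, microglia and macrophages, endothelium, pericytes with smooth muscle and fibroblasts, ependyma with choroid plexus, and red blood cells. No member of the red blood cell list passed the filter in any comparison, so it has no result. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. The alternatives were camera with an estimated correlation, and fry, which tests a list against no change and not against other genes. No camera call in any of the 5 comparisons held with an estimated correlation.

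The rule for named genes took 15 genes fixed in advance wherever tested, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 and no overlap between groups (leaving out predicted genes, small RNAs and sex-linked genes), and up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. Overlaps were tested with Fisher's exact test, two-sided, among genes tested in both fits. Where 2 comparisons shared libraries, 100 simulations of unchanged groups gave the value expected without any effect. Gene positions are those of the RefSeq annotation of mm10, which matched 22550 of the 24062 gene names by symbol. Alternatives covered scaling, the filter, the pseudocount, library weights, a replicate block, the libraries in the fit, small RNAs and the leaving out of each library in turn. The alternatives that need counts, a second count-based test and thinning to equal depth, could not be run.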

Results

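RNA sequencing profiled EGFP-positive cells sorted from the dentate gyrus of Nestin-EGFP mice that had received midazolam or water on postnatal days 7 to 9. It covered Control P10 and MDZ P10 at postnatal day 10, and Control 8w, MDZ 8w and RUN MDZ 8w (exposed mice with a running wheel) at 8 weeks. Cultured neural stem cells with or without added Egr1, a zinc finger transcription factor of the immediate early class, were profiled as well. Each group had 3 libraries, with Control 8w replicates 2 and 3 counted as 1 sample because they differed by less than any other 8-week pair (n = 2). Any fit without Control 8w replicate 1 therefore leaves that group with 1 sample, assumed to vary like the other groups. All 8-week p-values assume one spread for the 3 groups, although the Control 8w samples differed more from each other than those of the other groups. A P10 library held 17620 to 18470 genes above 0 and a culture library 15540 to 16000. At 8 weeks the number was 11160, 11400 and 11250 in Control 8w, against 15380 to 16710 in MDZ 8w and 15570 to 15910 in RUN MDZ 8w. Levels are given as mean ± SD in FPKM at P10 and in TPM elsewhere, and changes as log2 fold changes ± SE from limma-trend on log2(value + 1), a scale that understates the changes of genes near 0.

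**Figure D1:**
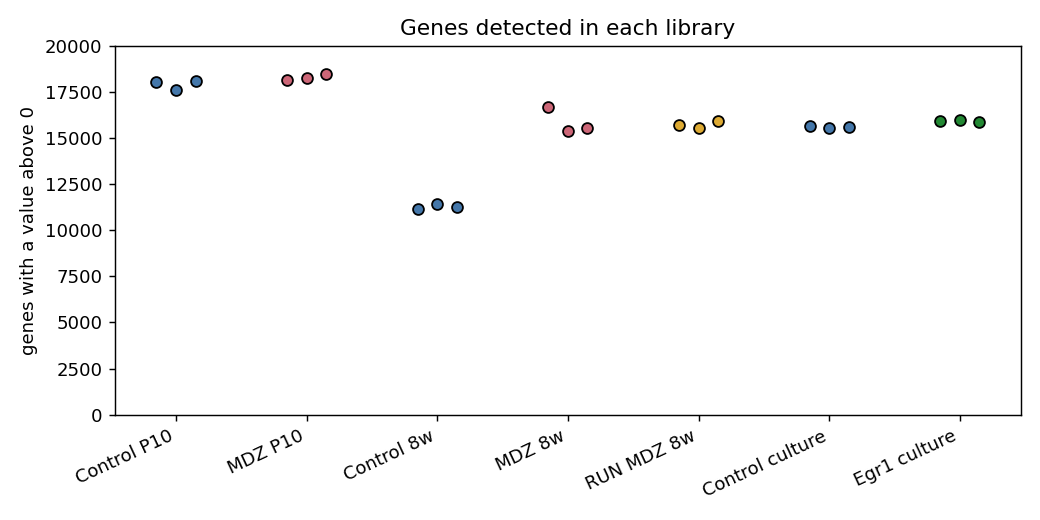
Number of genes with a value above 0 (vertical axis, starting at 0) in each of the 21 libraries, by group (horizontal axis), 1 point per library. The 3 Control 8w libraries lie at 11160, 11400 and 11250 genes, below every other library.

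The first comparison asked how midazolam altered the stem cell population 1 day after the last injection. Igsf1, an X-linked gene for a membrane glycoprotein of the immunoglobulin superfamily (mm10 chromosome X, 49782536 to 49797907), fell from 9.34 ± 0.687 FPKM in Control P10 to 4.94 ± 0.231 FPKM in MDZ P10 (n = 3 each), a log2 change of -0.80 ± 0.07 (limma adjusted p = 0.033). It was the single gene of 12914 to pass, and it did so without Control P10 replicate 2 but not without any other one of the 6 libraries (adjusted p 0.0538 to 0.377), nor with median-of-ratios scaling (adjusted p = 0.0522). Egr1 (chromosome 18, 34861207 to 34864956) stood at 263 ± 29.7 FPKM in MDZ P10 and 171 ± 19.2 FPKM in Control P10. Every MDZ P10 library lay above every Control P10 library, but the gene did not pass over all genes (limma log2 0.62 ± 0.11, adjusted p = 0.21). Nab2, which encodes a corepressor that binds Egr proteins and is itself induced by them, measured 6.58 ± 0.585 against 3.91 ± 0.162 FPKM (log2 0.62, adjusted p = 0.072).

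Among the lists, 24 of 26 measured immediate early genes had a positive change in MDZ P10, with a median of 0.30. None passed over all genes and 15 passed as higher when adjusted over the list alone. Ier2 (77.3 ± 9.13 against 49.2 ± 6.94 FPKM) and Nr4a1 (70.8 ± 12.5 against 45.1 ± 3.01 FPKM) had log2 changes of 0.64 and 0.63. camera placed the list above other genes (adjusted p = 1.5e-10, but adjusted p = 0.70 with an estimated correlation). Of 32 S phase genes, 30 were positive (median 0.16), 0 passed over all genes and 7 passed adjusted over the list alone. Pcna, the replication clamp, was at 43.1 ± 1.74 against 36.1 ± 0.991 FPKM for example, and camera set the list apart (adjusted p = 6.1e-08, adjusted p = 0.85 with an estimated correlation). The EGF, FGF and MAP kinase feedback list had 0 of 20 past the threshold over all genes and 6 higher adjusted over the list alone, Spry4, Dusp6 and Myc leading (log2 0.57, 0.32 and 0.32; camera adjusted p = 2.1e-05, adjusted p = 0.35 with an estimated correlation). Glycolysis genes had 0 and 2 by the same counts (camera adjusted p = 0.032, adjusted p = 0.85 with an estimated correlation), and were no longer set apart without Control P10 replicate 2 or MDZ P10 replicates 1 or 3 (adjusted p 0.161, 0.0935 and 0.0693).

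All 16 measured pericyte, smooth muscle and fibroblast genes had a negative change in MDZ P10 (median -0.28), with 0 past the threshold over all genes and 6 lower adjusted over the list alone. Col3a1, a fibrillar collagen, measured 5.22 ± 2.52 against 11.1 ± 2.45 FPKM and Vtn, vitronectin, 43.7 ± 5.2 against 58.1 ± 5.75 FPKM (camera adjusted p = 1.0e-09, adjusted p = 0.65 with an estimated correlation). Mature oligodendrocyte markers had a median of -0.22 (0 past either adjustment, camera adjusted p = 0.0069, adjusted p = 0.85 with an estimated correlation). Mbp stood at 373.6 FPKM in Control P10 replicate 2 against 184.7 and 188.2 FPKM in the other two. Without that library the direction of the list turned (adjusted p = 0.30), and without MDZ P10 replicate 3 the list was not set apart (adjusted p = 0.10). The list's median was 0.11 and -0.12 without these 2, and -0.44, -0.35 and -0.32 without Control P10 replicate 1, Control P10 replicate 3 and MDZ P10 replicate 2. Neuroblast markers (median -0.12, camera adjusted p = 0.016) and mature astrocyte markers (median -0.04, camera adjusted p = 0.021) had 0 members past either adjustment (adjusted p = 0.85 for both with an estimated correlation). The neuroblast list was lost without Control P10 replicates 1 or 3 or MDZ P10 replicates 1 or 2 (adjusted p 0.103 to 0.346), and the astrocyte list without Control P10 replicate 1 or MDZ P10 replicate 1 (adjusted p 0.841 and 0.127). Without 1 library at a time the neuroblast median ran from -0.24 (Control P10 replicate 2) to -0.0059 (Control P10 replicate 3), and the astrocyte median from -0.087 (Control P10 replicate 3) to 0.043 (Control P10 replicate 1). The remaining 18 lists were not set apart by camera (adjusted p 0.10 to 0.92). GABA receptor and handling genes, the class on which midazolam acts, were among them with 0 members past either adjustment. So were radial glia markers, in which Nes, Sox2, Gfap and Hopx had log2 changes of -0.07, 0.05, 0.06 and 0.13, and G2/M genes, with Mki67 at -0.14 and Top2a at -0.02. Adjusted over the list alone, Notch, BMP and Id genes and known Egr1 targets each had 3 higher and 1 lower, endothelial markers 2 higher and ligands linked to running 1 higher. Hes1 and Hes5 of the Notch list were at 0.59 (adjusted p = 0.20). Of the remaining genes fixed in advance, Eomes, Neurod1, Dcx and Mcm2 lay between -0.26 and 0.18.

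At an unadjusted p below 0.05 the P10 comparison had 1575 genes, 1103 of them higher, where 645.7 are expected by chance, and the 2 groups did not overlap for 18.76% of genes (10% by chance). Without Control P10 replicate 2, limma called 93 genes higher and 8 lower, and without Control P10 replicates 1 or 3 or MDZ P10 replicates 1 or 2 it called 0. Control P10 replicate 1 was also the single P10 library with female-type expression, Xist at 158.9 FPKM and Ddx3y at 0.032 FPKM, and with the ratio of Y-linked genes to Xist as a covariate 0 genes passed.

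**Figure D2:**
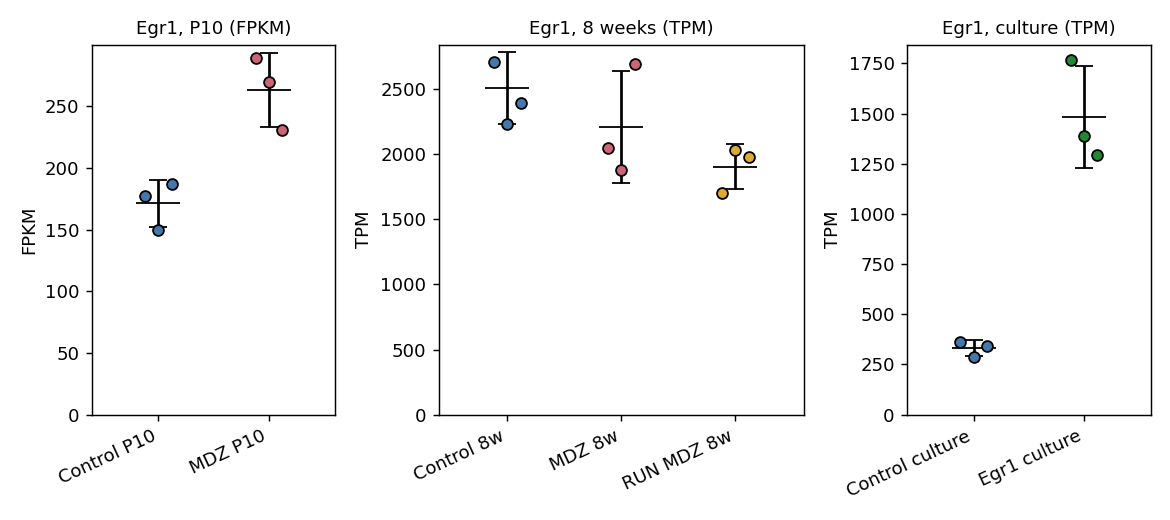
Egr1 level (vertical axis, FPKM at P10 and TPM at 8 weeks and in culture, each starting at 0) in each library by group, with the mean as a horizontal line and the SD as a bar. The Control 8w mean and SD use the mean of replicates 2 and 3 as 1 sample. Egr1 was 263 FPKM in MDZ P10 against 171 FPKM in Control P10, and 1483 TPM in Egr1 culture against 330 TPM in Control culture.

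The second comparison asked which changes were present at 8 weeks. Neuroblast genes fell in MDZ 8w: Neurod1, a transcription factor of differentiating granule neurons (chromosome 2, 79452637 to 79456636), from 968 ± 62.9 TPM in Control 8w (n = 2) to 473 ± 84.3 TPM (n = 3; log2 -1.05 ± 0.19, adjusted p = 0.022). Nhlh1 fell from 279 ± 18.8 to 132 ± 24.9 TPM (log2 -1.09, adjusted p = 0.026) and Prox1, a granule neuron fate factor, from 431 ± 47.1 to 231 ± 35.6 TPM (log2 -0.90, adjusted p = 0.036). Of the 25 measured members of that list, 0 rose, 3 fell and 22 did not pass, with 4 lower adjusted over the list alone (median -0.44, camera adjusted p = 2.7e-08, adjusted p = 0.49 with an estimated correlation). Radial glia genes rose: Hopx (chromosome 5, 77086986 to 77115123), a marker of quiescent stem cells, from 111 ± 24.1 to 352 ± 36.6 TPM (log2 1.67 ± 0.29, adjusted p = 0.019). Fabp7 rose from 464 ± 7.07 to 1267 ± 268 TPM (log2 1.43, adjusted p = 0.014) and Fgfr3 from 23.6 ± 11.2 to 85.1 ± 11.1 TPM (log2 1.88, adjusted p = 0.016). In that list 4 of 24 rose and 0 fell, with 5 higher adjusted over the list alone (median 0.57, camera adjusted p = 0.034, adjusted p = 0.49 with an estimated correlation). Neurod1, Nhlh1 and Fabp7 did not pass without MDZ 8w replicates 1 or 2 (adjusted p 0.0937 and 0.0891 for Neurod1), nor Hopx, Fgfr3 and Prox1 without any one MDZ 8w library (adjusted p 0.0847, 0.0824 and 0.0677 for Hopx). Prox1 was also lost without RUN MDZ 8w replicates 1 or 3, which share in the estimate of spread (adjusted p 0.0601 and 0.0517). With library quality weights none of these 6 genes passed (adjusted p 0.277 to 0.662), and Neurod1, Nhlh1 and Prox1 did not pass after quantile normalization (adjusted p 0.068, 0.0794 and 0.103). The radial glia list was not set apart with median-of-ratios scaling (adjusted p = 0.0519) or without Control 8w replicate 1, MDZ 8w replicate 2 or RUN MDZ 8w replicate 3 (adjusted p 0.147, 0.0525 and 0.0614).

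Mature astrocyte markers had 2 of 20 higher and 7 higher adjusted over the list alone (median 0.63, camera adjusted p = 0.031, adjusted p = 0.49 with an estimated correlation), among them Mlc1 at 428 ± 53.6 against 137 ± 16.8 TPM (log2 1.63, adjusted p = 0.0033). Id4, a BMP-induced inhibitor of differentiation, rose from 50.5 ± 1.28 to 231 ± 14.8 TPM (log2 2.17 ± 0.24, adjusted p = 0.0035). Mlc1 and Id4 passed whichever library was left out but not with library quality weights (adjusted p 0.227 and 0.161). The astrocyte list was lost without RUN MDZ 8w replicate 3 (adjusted p = 0.058), and its median was 1.02 without Control 8w replicate 1. Of 14 ependymal and choroid plexus genes 5 were higher and 0 lower, and 5 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 0.60). Among them Foxj1, a regulator of motile cilia, was at 11.1, 7.58 and 6.98 TPM in MDZ 8w replicates 1 to 3 and listed at 0 in each Control 8w library, as were Tmem212, Ccdc153 and Dynlrb2 (means of 14.4, 14.4 and 13.1 TPM in MDZ 8w). These 4 did not pass with library quality weights (adjusted p 0.230 to 0.519) or after quantile normalization (adjusted p 0.102 to 0.327), nor Foxj1 and Ccdc153 without MDZ 8w replicates 1 or 2 (adjusted p 0.0642 to 0.0866), nor Foxj1 without replicate 3 (adjusted p = 0.0609). Foxj1 and Ccdc153 were also lost with a pseudocount of 5 (adjusted p 0.103 and 0.0905). In the G2/M list 33 of 34 genes were positive (median 1.55), with 2 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0069, adjusted p = 0.50 with an estimated correlation). Its called members, Aurka and Nusap1, averaged 1.04 and 1.52 TPM in Control 8w, near the floor of detection, and neither passed without any one MDZ 8w library (adjusted p 0.0787 to 0.130), nor Nusap1 without RUN MDZ 8w replicate 1 (adjusted p = 0.0595). The list was lost without Control 8w replicate 1, where its median was 0.55, or MDZ 8w replicate 2 (adjusted p 0.106 and 0.0537). Mki67 (58 ± 13.5 against 42.9 ± 1.28 TPM) and Top2a (80.7 ± 31.1 against 75.7 ± 5.49 TPM), which were well detected in both groups, did not pass. Pericyte, smooth muscle and fibroblast genes had 1 of 17 lower, Vtn at 680 ± 245 against 2263 ± 308 TPM, and 4 lower adjusted over the list alone (median -0.88, camera adjusted p = 6.4e-05, adjusted p = 0.50 with an estimated correlation). That list's mean log2 value was 5.99 in Control 8w replicate 1 and 3.93 in the sample of replicates 2 and 3, and without replicate 1 it was no longer set apart (median -0.031, adjusted p = 0.48). In all, 21 lists were not set apart by camera (adjusted p 0.055 to 0.90). The endothelial list had 1 gene higher and 1 lower, by either adjustment. Tie1, an endothelial receptor kinase, was at 12.2, 13.0 and 11.5 TPM in MDZ 8w against 0.0381, 0 and 0 TPM in Control 8w (adjusted p = 0.0048, but 0.207 with library quality weights and 0.346 after quantile normalization). Cdh5, the endothelial cadherin, fell from 36.7 ± 1.62 to 10.2 ± 1.56 TPM (log2 -1.76, adjusted p = 0.020), though not without any one MDZ 8w library (adjusted p 0.0672 to 0.0847). Cdh5, Vtn, Aurka and Nusap1 were also lost with library quality weights (adjusted p 0.426 to 0.655), and the last 3 after quantile normalization (adjusted p 0.0611, 0.217 and 0.241). Egr1 measured 2207 ± 428 TPM in MDZ 8w and 2509 ± 278 TPM in Control 8w (log2 -0.20 ± 0.19, adjusted p = 0.57). Nes reached log2 1.59 ± 0.44 without passing (adjusted p = 0.085), and Sox2, Gfap, Eomes, Dcx, Mcm2 and the CDK inhibitors Cdkn1a, Cdkn1b and Cdkn1c did not pass either.

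In total 714 genes were higher and 69 lower of 15264 tested in MDZ 8w against Control 8w, with 3476 at an unadjusted p below 0.05. Of the 714, 61.2% were listed at 0 in both Control 8w samples and 82.2% in at least 1, against 17.6% of all tested genes listed at 0 in both. The leading rises were of this kind. Il18 was at 179.6, 92.31 and 120.3 TPM in MDZ 8w replicates 1 to 3, Snf8, a subunit of the endosomal ESCRT-II complex used by all cells, at 94.31, 87.48 and 84.88 TPM, and Ntm at 79.11, 38.54 and 55.21 TPM, and all 3 were listed at 0 in each Control 8w library. Rab26os, Coq6 and Dnajc24 followed, and no fold is given for any of them. Among the genes that fell most were Hrct1 (4.27 ± 2.15 against 82.1 ± 18.3 TPM), Cbr2 (1.64 ± 1.15 against 33.9 ± 14.3 TPM), Rtn4rl2, Casq2 and Rasgrp4. Each of these 5 was lost without MDZ 8w replicate 1 and without MDZ 8w replicate 2 (adjusted p 0.0504 to 0.148), and Rab26os without any one MDZ 8w library (adjusted p 0.0704 to 0.0878). The groups did not overlap for 39.14% of genes (20% by chance for 3 against 2). The median change of all genes was 0.36, and -0.06 after quantile normalization, where 124 genes were higher and 28 lower. The count was 19 with library quality weights, 19 higher and 0 lower, with Rab26os, Ntm and Dnajc24 no longer called (adjusted p 0.456, 0.0612 and 0.104). Rab26os, Rtn4rl2 and Casq2 did not pass after quantile normalization (adjusted p 0.0509, 0.102 and 0.0506), nor Cbr2 with a pseudocount of 0.1 (adjusted p = 0.109). The count was 207, 294 and 281 without MDZ 8w replicates 1, 2 and 3. Without Control 8w replicate 1 it was 2928, from a control group of 1 sample that has no spread of its own.

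The third comparison asked what running changed in exposed mice. Genes of blood vessels rose in RUN MDZ 8w against MDZ 8w: Acta2, smooth muscle actin (chromosome 19, 34240336 to 34255585), from 23.4 ± 4.44 to 165 ± 45.6 TPM (log2 2.74 ± 0.31, adjusted p = 0.027; n = 3 each). Flt1, a VEGF receptor, rose from 20.1 ± 3.9 to 89.7 ± 5.98 TPM (log2 2.12, adjusted p = 0.031), Cldn5, a tight junction protein, from 150 ± 7.76 to 406 ± 64 TPM (log2 1.42, adjusted p = 0.032), and Abcb1a, Cdh5 and Ptprb by 1.99, 2.27 and 2.45. All 18 endothelial genes were positive (median 1.56), with 4 past the threshold over all genes and 13 adjusted over the list alone (camera adjusted p = 5.4e-18, adjusted p = 0.069 with an estimated correlation). Pericyte, smooth muscle and fibroblast genes were all positive too (17 of 17, median 1.74), with 1 and 8 past the threshold by the same counts (camera adjusted p = 4.4e-10, adjusted p = 0.22 with an estimated correlation). The heat shock gene Hspa1b (log2 2.27) and Ccdc81 (log2 3.99) completed the 8 genes that rose. Of the 16 that fell, 15 were microRNA or small nucleolar RNA genes, and the other was Ndufa1, a subunit of mitochondrial complex I (43.5 ± 8.97 against 143 ± 13.9 TPM, log2 -1.71, adjusted p = 0.043).

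Other lists differed in direction. S phase genes had 32 of 33 negative changes in RUN MDZ 8w (median -0.67), with 0 past the threshold over all genes and 1 lower adjusted over the list alone. Mcm5 was at 39.3 ± 9.35 against 90.4 ± 13.9 TPM, and camera set the list apart (adjusted p = 4.4e-10, adjusted p = 0.12 with an estimated correlation). Microglia markers had a median of -0.90 (0 over all genes, 2 lower adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.45 with an estimated correlation). Mature oligodendrocyte markers had a median of 1.90 and 6 higher adjusted over the list alone, with Mbp at 246 ± 57.1 against 38.5 ± 20.4 TPM (camera adjusted p = 9.6e-08, adjusted p = 0.22 with an estimated correlation). The ependymal list had a median of 2.21 and 5 higher adjusted over the list alone (camera adjusted p = 8.8e-07), and mature astrocyte markers a median of 0.72 and 3 higher (camera adjusted p = 5.3e-07); with an estimated correlation the adjusted p was 0.22 and 0.12. The ependymal list's mean log2 value was 5.90 in RUN MDZ 8w replicate 2 against 3.48 and 3.64 in replicates 1 and 3 and 2.09 to 2.61 in MDZ 8w. Without that library, the single RUN MDZ 8w library with abundant Ttr (3552 against 0.119 and 0.208 TPM), the mean difference was 1.16 in place of 1.94 and the median 1.59 (camera adjusted p = 0.0068). None of the oligodendrocyte, ependymal and astrocyte members passed over all genes. camera also placed oligodendrocyte precursor, GABA, running-linked ligand and interferon lists higher (medians 0.98, 0.40, 0.36 and 0.78), and G2/M, cholesterol, chromatin and sex-linked lists lower (medians -0.26, -0.33, -0.10 and -3.69), with adjusted p between 0.217 and 0.452 with an estimated correlation. Their members past the threshold adjusted over the list alone numbered 1, 0, 3 and 2 higher for the first 4, and 0, 0, 0 and 3 lower for the last 4, against 1 over all genes in the ligand list and 0 in the others. Without MDZ 8w replicate 2 the G2/M, cholesterol, chromatin, ligand and microglia lists were lost (adjusted p 0.473, 0.376, 0.105, 0.0565 and 0.0565). Without RUN MDZ 8w replicate 1 the G2/M, cholesterol, ligand, microglia, GABA, oligodendrocyte precursor and sex-linked lists were lost (adjusted p 0.0674 to 0.221). G2/M and chromatin were lost without RUN MDZ 8w replicate 2 (adjusted p 0.065 and 0.123) or 3 (adjusted p 0.0731 and 0.0734), the ligand list without RUN MDZ 8w replicate 2 (adjusted p = 0.0778), and chromatin without MDZ 8w replicate 3 or Control 8w replicate 1 (adjusted p 0.0732 and 0.0577) or with quantile normalization (adjusted p = 0.054). Without MDZ 8w replicate 2 and RUN MDZ 8w replicate 1 in turn, the microglia median was -0.47 and -0.32 and the oligodendrocyte precursor median 0.53 and 0.61, and without MDZ 8w replicate 2 the G2/M and cholesterol medians were -0.024 and -0.10. The chromatin median was -0.043 and -0.060 without the same pair. The precursor and G2/M medians were 1.56 and -0.43 without MDZ 8w replicate 1, and that of G2/M -0.13 and -0.16 without RUN MDZ 8w replicates 2 and 3. The interferon median was 0.41 without RUN MDZ 8w replicate 3. The sex-linked shift followed Ddx3y, at 0 TPM in RUN MDZ 8w replicates 1 and 3 and 29.06 TPM in replicate 2. Uty and Eif2s3y were also at 0 TPM in replicates 1 and 3, with Xist at 663.1 and 620.4 TPM. In MDZ 8w, Ddx3y ran from 51.28 to 72.31 TPM and Xist from 24.51 to 270.7 TPM. Female-type expression thus went in part with running. The other 11 lists were not set apart (adjusted p 0.052 to 0.74). Neurod1 (476 ± 62.1 against 473 ± 84.3 TPM), Egr1 (1904 ± 175 against 2207 ± 428 TPM), Hopx (208 ± 75.5 against 352 ± 36.6 TPM) and Eomes (195 ± 17.2 against 326 ± 56.3 TPM) did not pass.

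limma called 24 genes in this comparison. None of the 8 rises, nor Ndufa1, passed without any one MDZ 8w or RUN MDZ 8w library (Acta2 adjusted p 0.0653 to 0.128), nor Ccdc81 with a pseudocount of 0.1 (adjusted p = 0.104). Its log2 change was 5.87 with that pseudocount and 2.28 with one of 5. In all 1523 genes had an unadjusted p below 0.05, and the groups did not overlap for 24.9% of genes (10% by chance). The count was 0 without MDZ 8w replicate 1, 2 or 3. It was also 0 with small RNAs removed, with the replicate number as a block, and for genes with a mean of at least 50. It was 10, 16 and 13 without RUN MDZ 8w replicates 1, 2 and 3, 275 without Control 8w replicate 1 (with 1 control sample left in the fit), 432 with library quality weights, and 360 when only the 6 libraries compared were fitted. Quantile normalization gave 15 higher and 19 lower.

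**Figure D3:**
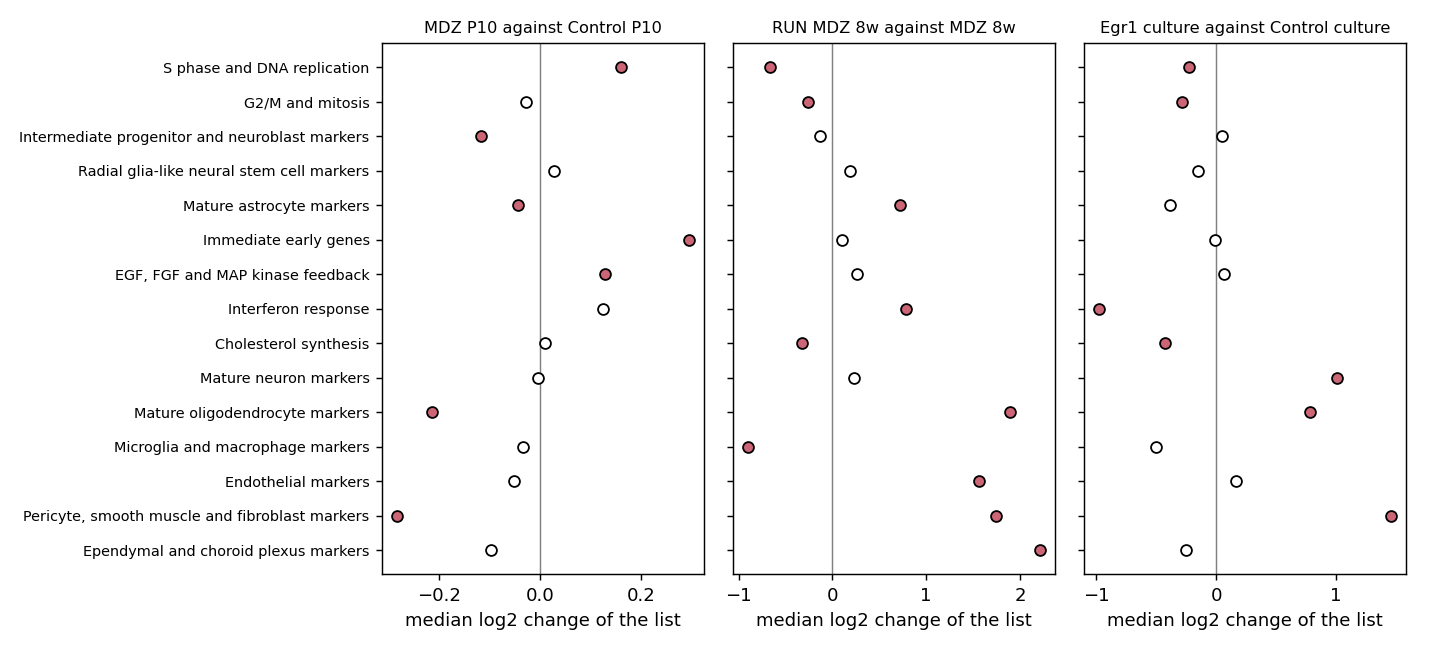
Median log2 change of each gene list (horizontal axis, a different scale in each panel) for 3 comparisons, with filled points where camera gave an adjusted p below 0.05 at its preset correlation and open points otherwise. With an estimated correlation no list passed. Pericyte, smooth muscle and fibroblast genes had medians of -0.28, 1.74 and 1.46, and S phase genes 0.16, -0.67 and -0.22, from left to right.

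Exposed running mice were then set against unexposed sedentary mice, a comparison in which midazolam and running change together. Sex-linked expression differed as well. Ddx3y was at 0 TPM in RUN MDZ 8w replicates 1 and 3, and at 48.62 to 58.19 TPM in the Control 8w libraries. Neuroblast genes fell: Nhlh1 from 279 ± 18.8 to 58.9 ± 4.27 TPM (log2 -2.23, adjusted p = 0.0017). Eomes, a marker of intermediate progenitors, fell from 510 ± 129 to 195 ± 17.2 TPM (log2 -1.36, adjusted p = 0.010), Neurod1 by -1.03 (adjusted p = 0.016) and Prox1 by -0.94 (adjusted p = 0.020). Of 25 list members 0 rose and 8 fell, with 9 lower adjusted over the list alone (median -0.44, camera adjusted p = 1.2e-08, adjusted p = 0.27 with an estimated correlation). Mature astrocyte genes rose, 12 of 20 over all genes and 15 adjusted over the list alone, among them Aqp4, the water channel of astrocyte endfeet (95.6 ± 42.8 against 11 ± 1.23 TPM, log2 2.93), and Slc1a2 (630 ± 57.7 against 246 ± 18.4 TPM, log2 1.35), with a camera adjusted p = 9.5e-06 and an adjusted p = 0.27 with an estimated correlation. Radial glia markers had 7 of 24 higher and 13 adjusted over the list alone, with Fgfr3 and Clu leading. Mature oligodendrocyte markers had 10 of 15 and 11, with Mag at 113.4, 191.1 and 204.1 TPM against 12.53, 0 and 0 TPM in Control 8w, and endothelial markers 10 of 18 and 11, with Abcb1a at log2 1.87. For these 3 lists camera gave an adjusted p of 0.0076, 5.4e-04 and 5.4e-04, and the adjusted p was 0.27, 0.39 and 0.30 with an estimated correlation. The radial glia list was lost without Control 8w replicate 1 (adjusted p = 0.0566), where the neuroblast median was -0.71. Also lost were Prox1 without RUN MDZ 8w replicate 1 (adjusted p = 0.0504) and Mag without RUN MDZ 8w replicates 2 or 3 (adjusted p 0.0551 and 0.0632). Neurod1, Prox1 and Mag did not pass after quantile normalization (adjusted p 0.0541, 0.0783 and 0.0505). With library quality weights none of the genes named for this comparison passed (adjusted p 0.18 to 0.558 for those above), and limma called 0 genes in all, as it did when only these 2 groups were fitted.

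Chromatin regulators (1 of 28 lower, Smarca4, 0 adjusted over the list alone, camera adjusted p = 0.0032) and sex-linked genes (0 of 5, 2 lower adjusted over the list alone, camera adjusted p = 0.043) were placed lower, with adjusted p of 0.27 and 0.39 with an estimated correlation. Both were lost without Control 8w replicate 1 (adjusted p = 0.0566 each), and the sex-linked list also without Control 8w replicate 2, MDZ 8w replicate 1 or RUN MDZ 8w replicates 1 or 3 (adjusted p 0.0507, 0.0504, 0.0803 and 0.0862). With median-of-ratios scaling the sex-linked list was lost (adjusted p = 0.057), and with quantile normalization both were (adjusted p 0.0877 for sex-linked and 0.0766 for chromatin genes). Smarca4 was lost without any one of 7 libraries (adjusted p up to 0.116), with a pseudocount of 5 (adjusted p = 0.0561) and with quantile normalization (adjusted p = 0.127). The other 19 lists were not set apart (adjusted p 0.059 to 0.83). The 6 leading rises, Il18, Tmem212, Tppp3, Ccdc153, Dynlrb2 and Ntm, were listed at 0 in every Control 8w library. Tmem212, Ccdc153 and Dynlrb2 belong to the ependymal list, in which 5 of 14 rose and 0 fell (camera adjusted p = 0.065). Ly6g5b, Cbr2, Slc25a34, Hist2h3b, Efcab11 and Hist1h4j fell most. Ly6g5b was listed at 0 in each RUN MDZ 8w library against 39.93, 15.79 and 21.52 TPM in Control 8w. The other 5 had log2 changes of -4.69 to -3.30, whose size depends on the pseudocount, since Cbr2 had -7.13 and -2.81 and Slc25a34 -6.07 and -2.21 with pseudocounts of 0.1 and 5. The last 4 of the 6 did not pass without any one MDZ 8w library (adjusted p 0.0554 to 0.0953). Slc25a34, Hist2h3b and Efcab11 were also lost with a pseudocount of 0.1 (adjusted p 0.0581, 0.0862 and 0.114). Altogether 1437 genes were higher and 290 lower, with 4146 at an unadjusted p below 0.05 and 35% of genes without overlap between the groups (20% by chance). The median change of all genes was 0.51, and -0.09 after quantile normalization, where 278 were higher and 128 lower. When only these 2 groups were fitted, or library quality weights were used, limma called 0. The count was 910, 987 and 942 without MDZ 8w replicates 1, 2 and 3, which share in the estimate of spread, and 3952 without Control 8w replicate 1, again with 1 control sample.

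Whether the midazolam change was undone by running was examined gene by gene. Of the 783 genes called in MDZ 8w against Control 8w, 16 were called the opposite way in RUN MDZ 8w against MDZ 8w, where independent lists would share 0.785. Of the 16, 15 were microRNA or small nucleolar RNA genes, which rose and then fell, and the other was Cdh5, which fell and then rose. The number of small RNA genes detected per library was 13 to 21 in Control 8w, 134 to 249 in MDZ 8w and 54 to 72 in RUN MDZ 8w, and with small RNAs removed limma called 0 genes in RUN MDZ 8w against MDZ 8w. Against Control 8w, 85.1% of the 783 were still called in RUN MDZ 8w and 14.9% were not. Both calls rest on the same Control 8w samples, and 61.2% of the 714 genes higher in MDZ 8w were listed at 0 in both. With library quality weights, or with only those 2 groups fitted, limma called 0 genes in RUN MDZ 8w against Control 8w. The share still called is therefore no measure of a lasting midazolam change. MDZ 8w against Control 8w and RUN MDZ 8w against MDZ 8w both use the MDZ 8w libraries, so their chance values are opposed. Across genes, which are not independent replicates, the fold changes had a correlation of -0.198 where unchanged groups gave -0.446, a covariance of -0.212 where they gave -0.233, and opposite signs for 51% where they gave 64.7%. The count of 16 became 0 without any one MDZ 8w library, 9 without RUN MDZ 8w replicate 1 and 63 without Control 8w replicate 1, with 1 control sample left. The MDZ 8w and RUN MDZ 8w changes against the same Control 8w samples had a correlation of 0.818 (0.60 for unchanged groups) and a covariance of 1.49 (0.351), and shared 631 rises and 35 falls, where independent lists would share 67.2 and 1.31. With 2 Control 8w samples these could not be split. The simulated groups did not include the lower detection in Control 8w, so part or all of the excess may come from the shared controls.

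The last comparison measured the response to Egr1 in culture. Egr1 itself was at 1769, 1390 and 1291 TPM in the Egr1 cultures and at 361, 285 and 344 TPM in the Control cultures, a log2 change of 2.16 ± 0.13 (adjusted p = 4.0e-06), which sums endogenous and introduced transcripts. The steepest rise was that of Dcn, the proteoglycan decorin (chromosome 10, 97479500 to 97518163), from 0.129 ± 0.0457 to 145 ± 19.1 TPM (log2 7.01 ± 0.11). Calb2, calretinin, rose from 1.13 ± 0.23 to 144 ± 16.8 TPM (log2 6.08), followed by Clec18a, Trh, Fam180a and Tnnc1 with log2 changes of 5.97, 5.96, 5.25 and 5.14. Such sizes depend on the pseudocount for genes near 0, as Fam180a had 8.01 and 3.13 with pseudocounts of 0.1 and 5. Lgals9, galectin-9, fell from 39.5 ± 1.3 to 6.16 ± 0.69 TPM (log2 -2.51), followed by Npvf, Gstt1, Htra3, Clic5 and Emp2 down to -1.90. Among stem cell genes, Nes (378 ± 51.7 against 189 ± 11.5 TPM, log2 0.99) and Gfap (5.73 ± 0.636 against 1.17 ± 0.251 TPM, log2 1.64) rose, while Sox2 fell by 0.27. Hopx rose by 0.32, though not without Control culture replicate 2 or Egr1 culture replicate 2 (adjusted p 0.0577 and 0.0646).

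Proliferation genes fell with Egr1. In the G2/M list 24 of 34 fell and 0 rose, with 27 lower adjusted over the list alone. Among them were Top2a (156 ± 17.6 against 222 ± 20.7 TPM, log2 -0.51), Birc5 (-0.37) and Mki67 (-0.42), and the list had a median of -0.28 (camera adjusted p = 0.0017, adjusted p = 0.92 with an estimated correlation). In the S phase list 17 of 33 fell and 1, E2f1, rose, by either adjustment (median -0.22, camera adjusted p = 0.011, adjusted p = 0.92 with an estimated correlation). Mcm2 was at -0.25 and Tk1 at -0.35, and across the alternatives these falls were as small as -0.14 and -0.24. Mki67 did not pass with median-of-ratios scaling (adjusted p = 0.0629) or without Control culture replicates 2 or 3 or Egr1 culture replicate 3 (adjusted p 0.0619, 0.119 and 0.0548), Mcm2 not with median-of-ratios scaling (adjusted p = 0.0628), and the S phase list was lost without Control culture replicate 2 (adjusted p = 0.0673). The CDK inhibitors Cdkn1a (722 ± 24 against 517 ± 31.2 TPM, log2 0.48), Cdkn1b (0.25) and Cdkn1c (0.89, but 1.57 and 0.31 with pseudocounts of 0.1 and 5) rose, and their list had 8 higher and 5 lower of 20, also adjusted over the list alone (camera adjusted p = 0.060). Interferon response genes fell, 17 of 18 by either adjustment, such as Bst2 (12.6 ± 0.897 against 46.8 ± 4.52 TPM, log2 -1.81), Usp18 (-1.57) and Ifitm3 (-1.02), while Isg15, a ubiquitin-like modifier, rose by 1.44 (median -0.98, camera adjusted p = 4.7e-05, adjusted p = 0.55 with an estimated correlation). Cholesterol synthesis genes fell, 16 of 20 with 1 rise by either adjustment, including Mvk (-0.70), with a median of -0.43 (camera adjusted p = 0.0017, adjusted p = 0.92 with an estimated correlation).

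Notch, BMP and Id genes went both ways, 10 higher and 5 lower of 22 by either adjustment, with Hey1 (117 ± 4.37 against 25 ± 1.51 TPM, log2 2.18) and Id2 (1.29) higher and Nrarp (-0.91), a Notch feedback gene, lower (camera adjusted p = 0.019, adjusted p = 0.91 with an estimated correlation). Mature neuron markers rose, 7 of 10 over all genes and 8 adjusted over the list alone, with Nrgn, neurogranin, at 418 ± 44.5 against 33.6 ± 1.86 TPM (log2 3.59) and Syt1 and Snap25 at 2.27 and 2.30 (1.25 and 0.90 with a pseudocount of 5). Mature oligodendrocyte markers had 6 of 7 higher and 1 lower (Cnp at 0.97 and Trf at 0.78, but Aspa at 4.41 ± 0.285 against 9.89 ± 1.73 TPM), and pericyte, smooth muscle and fibroblast genes 4 of 5 higher (Acta2 at 2.14), by either adjustment. For these 3 lists the camera adjusted p was 5.0e-05, 0.0022 and 0.0012, and the adjusted p was 0.55 with an estimated correlation. The other 17 lists were not set apart (adjusted p 0.060 to 0.93). Higher and lower genes numbered 5 and 7 of 23 known Egr1 targets, 7 and 12 of 26 immediate early genes, 8 and 7 of 22 MAP kinase feedback genes, 7 and 8 of 20 radial glia markers, 7 and 3 of 20 p53 targets and 6 and 10 of 19 fatty acid oxidation genes. Adjusted over the list alone these counts differed only in 8 lower Egr1 targets and 9 higher immediate early genes. In all, 1888 genes rose and 3598 fell of 12402, with 481 and 279 of them at least 1 on the log2 scale, and the groups did not overlap for 55.5% of genes (10% by chance). The median change of all genes was -0.10 and moved to 0.01 with median-of-ratios scaling, which gave 2775 higher and 2723 lower, and quantile normalization gave 2452 and 3214. Small RNA genes held 12.1% to 14.5% of TPM in the culture libraries. Without Egr1 culture replicate 1, 2 or 3, or with median-of-ratios scaling, the Notch, BMP and Id list was no longer set apart (adjusted p 0.098, 0.073, 0.078 and 0.063).

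The culture response was compared with the changes in mice. Of 585 genes that rose in MDZ 8w and were tested in both, 81 also rose with Egr1, where independence gives 86.55 (odds ratio 0.92, Fisher's exact adjusted p = 0.96), and of 48 that fell, 19 also fell with Egr1, where 14.1 are expected (odds ratio 1.58, Fisher's exact adjusted p = 0.42). These 100 shared genes became 25, 33 and 30 without MDZ 8w replicates 1, 2 and 3, and 415 without Control 8w replicate 1, with 1 control sample left. Spearman's rho of the log2 changes was -0.03 across genes, which are not independent replicates. Of the genes changed by running within exposed mice, 1 rose and 1 fell in both, against 0.296 and 3.23 expected (Fisher's exact adjusted p = 0.59 and 0.49). That overlap was 0 without any one MDZ 8w or RUN MDZ 8w library and 48 without Control 8w replicate 1, likewise with 1 control sample. An overlap outside the plan took the genes called in RUN MDZ 8w against Control 8w. Its rises included 325 that fell with Egr1, against 282 expected (odds ratio 1.25, Fisher's exact adjusted p = 0.0078). Another 155 rose with Egr1, against 142 expected (Fisher's exact adjusted p = 0.51). Among its falls 60 also fell and 30 rose, against 77.86 and 39.21 expected (Fisher's exact adjusted p = 0.056 and 0.36). limma called 0 genes in that comparison with library quality weights or with only the 2 groups fitted, so this overlap depends on the fit. Fisher's exact p-values were adjusted over all overlaps tested, among them those between comparisons that shared libraries. The very small p-values of the latter lowered the adjusted p of 0.0078, whose Fisher's exact p was 0.0017 before adjustment. Igsf1 did not pass the filter in culture, so no called P10 gene could be compared there. Between P10 and 8 weeks 0 called genes were shared, which tells little, since only 1 gene was called at P10. Independence gives 0.053 shared with the 8-week rises and 0.0048 with the 8-week falls. At an unadjusted p below 0.05 limma had 1575 genes at P10 and 3476 at 8 weeks (rho of the log2 changes 0.04). Without Control P10 replicate 2, 8 genes were shared between the ages.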

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

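All tests of explanations in this part were chosen after the results were seen, as was the separate spread for each age; the test of a difference between ages and the other splits of the libraries had been set down in advance.

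The change from control to midazolam libraries differed between 8 weeks and P10 for 878 of 14350 genes by limma, 799 higher and 79 lower at 8 weeks. At an unadjusted p below 0.05 there were 3433. Of the 878, 740 had been called at 8 weeks and 0 at P10. The 8-week calls cannot be told apart from the lower detection in Control 8w. Age also went with the number of mice and cells per library. With library quality weights or quantile normalization the count was far lower, as given further below. Neurod1, a neuroblast transcription factor, had a difference of -0.92 ± 0.25 (SE, log2, adjusted p = 0.040), with changes of -1.05 at 8 weeks and -0.10 at P10. Hopx, a radial glia marker, had a difference of 1.57 ± 0.32 (adjusted p = 0.018). The differences of Egr1 (-0.79, adjusted p = 0.053) and Nes (1.68, adjusted p = 0.064) did not pass. The single spread for both ages had been set down in advance. It made more false calls (59 against 5) on data simulated with a separate spread per age. With it limma called 2696 genes, and Egr1 and Nes both passed (adjusted p 0.041 and 0.037). The count fell to 254, 329 and 333 without MDZ 8w replicates 1, 2 and 3 and rose to 2961 without Control 8w replicate 1, which leaves 1 control sample assumed to vary like the other groups, and it shares the Control 8w samples with the pattern that follows.

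More genes were higher than lower in MDZ 8w against Control 8w, 714 against 69. A candidate explanation is incomplete detection in the Control 8w libraries, where 61.2% of the 714 genes were listed at 0 in both samples. The share of genes called higher was 2.15% at an MDZ 8w mean of at least 100 TPM against 6.92% between 10 and 50 TPM and 13.7% between 5 and 10 TPM, but 0.319% between 1 and 5 TPM, where 90.9% of genes were listed at 0 in a control sample and the pseudocount limits the size of a change. When only the 5372 genes with a mean of at least 50 TPM over all 8-week samples were tested, limma called 32, 26 higher and 6 lower, and 5 of the 32 were listed at 0 in a Control 8w sample. A midazolam effect lasting to 8 weeks cannot be told apart from the difference in detection for these genes, because the libraries that detected fewer genes are the whole control group.

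Markers of vessels, oligodendrocytes and ependyma lay higher in RUN MDZ 8w than in MDZ 8w. A lower share of the main sorted cell type, with all other cells up in equal proportion, would raise microglia markers as well. The endothelial mean minus the microglia mean was higher in RUN MDZ 8w by 2.6 ± 0.536 (SE, log2), which argues against such an equal rise alone. Within Control 8w, however, the microglia mean was 0.90 and 3.38 in the 2 samples while the endothelial mean was 4.76 and 4.935. The microglia list was also not set apart without MDZ 8w replicate 2 or RUN MDZ 8w replicate 1. A lower share with uneven carry-over of other cells therefore cannot be decided by this difference. Library preparation that differed between the groups stays open, since the highest number of small RNA genes detected was 72 in RUN MDZ 8w and the lowest in MDZ 8w was 134, and preparation cannot be told apart from running because no other group ran. A real change in vessel cells, or in their share among sorted cells, with running was not tested by any value here. Ddx3y, Uty and Eif2s3y were at 0 TPM in RUN MDZ 8w replicates 1 and 3 and above 0 in every MDZ 8w library. A part played by the sex of the mice was not tested. As to chance, limma called 24 genes in the real grouping and at most 1 in the other splits of the 6 libraries, and 1 of the 10 splits reached 24, too few splits for a share below 0.05.

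Proliferation and interferon genes were lower with Egr1 in culture. Scaling to a common sum might lower many genes together, but with median-of-ratios scaling, which centres the typical gene, the G2/M median moved from -0.281 to -0.172 ± 0.0217 (SE over its genes) and the interferon median from -0.976 to -0.88 ± 0.158, which argues against scaling as the whole cause. An innate response to more lentivirus in the Egr1 cultures, which carried an added vector, would raise interferon genes. Their median was -0.976 ± 0.157 (SE over these genes). Each SE here measures the spread between genes of a list, which are not independent replicates, and not the spread between cultures. A direct or indirect effect of Egr1 stays open as a hypothesis, and neither list was set apart with an estimated correlation (adjusted p = 0.92 and 0.55). limma called 5486 genes in the real grouping and at most 4 in the other splits, and 1 of the 10 splits reached 5486, too few for a share below 0.05.

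For the P10 libraries the real grouping gave 1 gene and the other splits at most 0 by limma, so 1 of the 10 splits reached that count, and 10 splits are too few for a share below 0.05.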

How the results depend on the processing

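The pseudocounts, the filters at a mean of 10 and 50, quantile normalization, the removal of small RNAs, the separate handling of Control 8w replicates 2 and 3 and the leaving out of libraries for gene lists were chosen after seeing the data. Except where stated, the cause of a changed count was not tested. Stricter filters and a fold minimum test or admit fewer genes by construction, and fits without a library have fewer samples. Relative to the deepest library of each table, depth was 0.57 to 0.807 in the other P10 libraries and 0.901 to 0.966 in the other culture libraries. At 8 weeks it is unknown. The simulations did not vary depth, so what it limits was not measured. At 8 weeks the simulation missed most changes of 2 or less on the log2 scale. Fits without Control 8w replicate 1 leave Control 8w with 1 sample assumed to vary like the other groups.

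For MDZ P10 against Control P10, limma called 1 gene (1575 at an unadjusted p below 0.05). It called 0 with median-of-ratios factors, a mean of at least 10, the ratio of Y-linked genes to Xist as covariate, all mouse libraries in one fit, or an absolute log2 change of at least 1. It called 5 with library quality weights, 2 with a pseudocount of 5, 4 with quantile normalization, 5 with small RNAs removed and 2 with sex-linked genes left out. Leaving out a library gave 0 to 101, the highest without Control P10 replicate 2.

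The 783 genes of MDZ 8w against Control 8w became 19 with quality weights, 1410 and 461 with pseudocounts of 0.1 and 5, 492 and 32 with means of at least 10 and 50, 152 with quantile normalization, 1787 with Control 8w replicates 2 and 3 kept apart, and 4995 without the sample merged from them, which also leaves 1 control sample. Leaving out a library gave 207 (MDZ 8w replicate 1) to 2928 (Control 8w replicate 1). The 24 genes of RUN MDZ 8w against MDZ 8w became 38 with at least 1 TPM in at least 3 libraries, 432 with quality weights, 11 and 0 with means of at least 10 and 50, 0 with small RNAs removed, 122 with replicates 2 and 3 kept apart, 345 without the merged sample and 360 with only the libraries of the 2 groups. Leaving out a library gave 0 (each MDZ 8w library) to 275 (Control 8w replicate 1). The 1727 genes of RUN MDZ 8w against Control 8w became 0 with quality weights, 836 and 171 with the higher means, 406 with quantile normalization, 2904 with replicates kept apart, 5649 without the merged sample and 0 with only the 2 groups, and 910 (MDZ 8w replicate 1) to 3952 (Control 8w replicate 1) without a library.

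The 5486 genes of the culture comparison became 1515 at a mean of at least 50 and 760 at an absolute log2 change of at least 1, and 4383 to 5012 without a library. The 878 genes that differed between ages became 2696 with one spread, 17 with quality weights, 1467 and 510 with the pseudocounts, 459 and 42 with the higher means, 172 with quantile normalization and 1882 with replicates kept apart, and 254 (MDZ 8w replicate 1) to 2961 (Control 8w replicate 1) without a library. The 100 genes shared in direction by MDZ 8w and Egr1 became 21 at an absolute log2 change of at least 1, and 25 to 415 without a library. The 2 shared by the running change and Egr1 ranged from 0 to 48, the 0 shared by P10 and 8 weeks from 0 to 8, and the 16 that moved back from 0 to 63, again highest without Control 8w replicate 1 or, for P10, Control P10 replicate 2.

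Whether the replicate numbers mark pairs was not settled by their correlations. Between MDZ 8w and RUN MDZ 8w, replicates 1 and 2 correlated best with their own number (0.199 and 0.121, against -0.176 and -0.168 when crossed). Between Control 8w and MDZ 8w they did so at smaller values (0.0662 and 0.0682). No pair of groups had all 3 same-number correlations above 0.1 (-0.141, 0.139 and 0.135 at P10; 0.199, 0.121 and -0.0356 between MDZ 8w and RUN MDZ 8w), and not every sample correlated best with its own number. With the replicate number as a block the counts were 0 at P10, 164 for MDZ 8w, 0 for RUN MDZ 8w against MDZ 8w and 496 against Control 8w, 244 for the age difference, 19 and 0 for the overlaps of MDZ 8w and running with Egr1, and 0 for genes that moved back.

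Lists past the threshold numbered 8, 5, 15, 7 and 8 in the 5 comparisons, and 0 in each with an estimated correlation. With fry, which tests a list against no change, they numbered 0 at P10, 16 for MDZ 8w, 5 for RUN MDZ 8w against MDZ 8w and 17 against Control 8w. The median change of all genes was 0.36 for MDZ 8w and 0.51 for RUN MDZ 8w against Control 8w. The fry counts therefore do not measure lists set apart from other genes. With quantile normalization the lists that camera set apart numbered 13 for MDZ 8w and 11 for RUN MDZ 8w against Control 8w. Without a library they numbered 6 to 9, 2 to 9, 8 to 16, 6 to 9 and 7 to 8. The adjusted p of the mature oligodendrocyte list at P10 ranged from 1.8e-06 to 0.299 without 1 library, the last without Control P10 replicate 2, where its direction reversed, and was 0.853 with an estimated correlation and 0.878 with fry. Col1a1 in RUN MDZ 8w against Control 8w reversed from 2.80 to -0.28 with quantile normalization. In the other single genes named by the rule no call reversed.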

Other observations

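The gene sets built from the culture response and the list counts that follow were looked at after the main results were seen, whereas the lists themselves were fixed in advance.

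In RUN MDZ 8w against Control 8w, camera did not set apart the lists of immediate early genes, of Notch, BMP and Id genes, of GABA genes or of MAP kinase feedback genes, but some of their members passed. Over all 15264 genes tested, 1437 were higher and 290 lower. Immediate early genes had 9 of 28 higher and 1 lower, and 13 and 2 adjusted over the list alone, with Fosb at 926 ± 115 TPM (n = 3) against 164.5 ± 100.1 TPM (n = 2; log2 2.62, limma adjusted p = 0.0054) and Klf4 at 126 ± 13.3 against 36.9 ± 6.6 TPM (log2 1.75, adjusted p = 0.0050). Notch, BMP and Id genes had 7 of 29 higher and 0 lower, and 8 adjusted over the list alone, with Id1, a BMP target, at 147 ± 9.28 against 39.2 ± 15.3 TPM (log2 1.93, adjusted p = 0.0074) and Id4 at 176 ± 47.1 against 50.5 ± 1.28 TPM (log2 1.75). GABA receptor and handling genes had 7 of 27 higher and 9 adjusted over the list alone, with Slc6a11, a GABA transporter of astrocytes, at 175 ± 47.1 against 51.6 ± 1.86 TPM (log2 1.71, adjusted p = 0.0063). MAP kinase feedback genes had 2 of 23 higher and 2 lower, and 4 and 2 adjusted over the list alone. Their share of higher genes was close to that over all genes. In MDZ 8w against Control 8w, where 714 of 15264 genes were higher, the same lists, in this order, already had 5, 2, 2 and 2 higher and 0 lower. In RUN MDZ 8w against MDZ 8w, where 24 genes were called in all, 0 of their members passed over all genes by limma. Gadd45b, an activity-linked stress gene, fell from 110 ± 22.5 to 21.9 ± 4.52 TPM (log2 -2.28, adjusted p = 0.0055). None of these named genes passed with library quality weights (adjusted p 0.156 to 0.361), and limma called 0 genes in RUN MDZ 8w against Control 8w with those weights or when only the 2 groups were fitted, where 4146 had an unadjusted p below 0.05 in the fit of all 3 groups.

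Ttr, a transcript abundant in choroid plexus and chosen here after its values were seen, differed between libraries of the same group. It stood at 0.1209, 4481 and 4744 TPM in Control 8w replicates 1 to 3, at 1.1, 18.55 and 0.8318 TPM in MDZ 8w, and at 0.1191, 3552 and 0.2077 TPM in RUN MDZ 8w. The mean log2 value of the microglia list was 0.90 in Control 8w replicate 1 and 3.38 in the sample of replicates 2 and 3.

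Genes at least 2-fold higher with Egr1 in culture (397 tested at 8 weeks) and genes at least 2-fold lower (254) both lay above other genes in RUN MDZ 8w against MDZ 8w, with medians of 0.33 and 0.34 against 0.05 for all genes (camera adjusted p = 0.012 for each, adjusted p = 0.21 with an estimated correlation). In RUN MDZ 8w against Control 8w the Egr1-lower set lay above other genes (camera adjusted p = 0.017, adjusted p = 0.21 with an estimated correlation) and the Egr1-higher set was not set apart (camera adjusted p = 0.39). In MDZ 8w against Control 8w neither was (camera adjusted p = 0.39 for the lower and 0.55 for the higher set). In MDZ P10 against Control P10 neither set was set apart (camera adjusted p = 0.75 and 0.49).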
